A study of Cavia porcellus with 30 samples.

How the data were processed

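Poly-A enriched RNA libraries from guinea pig liver were prepared with a stranded kit and sequenced as paired ends, per the labels' protocols. Per the submitters' processing notes, the authors used kallisto 0.42.4, which assigns reads to annotated transcripts without aligning them to a genome; the transcript set and its release are not given in the sources used here. Each deposited table, per the file headers, holds a transcript identifier, its length, its effective length, its estimated count and its TPM. The estimated counts deposited by the authors are not normalized and need not be whole: 48.7% of the positive values were whole numbers within 1e-06. The TPM values deposited by the authors equalled the estimated count over the effective length, scaled to a fixed total, to within 0.000991% wherever TPM was at least 1. Identical identifiers stood in the same order in all 30 tables, and 1856 of 25824 transcripts were listed at 0 in every library. Reads shared between transcripts, whether of 1 gene or of near-identical genes, are divided by the estimate, so a change in a single transcript can be a change in how reads were divided.

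Groups came from the dose and duration labels, 5 animals in each of 6 groups. The series design describes 30 animals, so replicates were taken as separate animals; replicate numbers only name them. Every pair of libraries within a group differed by more than counting noise, the chi-square per degree of freedom over transcripts with at least 50 counts in the pair being 23.6 to 190 over 60 pairs, so no library was a copy of another of its group; pairs from different groups were not compared. No batch or date is given in the labels.

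Analyses were planned for sums of counts per gene. The reference table used here, of assembly mCavPor4.1 with 37416 genes, matched 0 of the transcript identifiers, so the planned fallback, a test per transcript, was used. The 38 gene lists fixed beforehand, the genes fixed by name and the tests of gene lists need gene names and were not run. No gene name was inferred from an identifier.

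Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr with its defaults (minimum count 10, minimum total 15) by group, which left 18239 transcripts holding 99.95% to 99.98% of the counts of each library. Scaling used TMM factors. Counts are relative within a library and no measure of the total RNA per liver was used here, so higher and lower refer to the share of the sequenced RNA after scaling. A single quasi-likelihood model with 1 coefficient per group was fitted to all 30 animals (robust dispersion and robust quasi-likelihood, 24 residual degrees of freedom), and 9 contrasts were tested: each dose against vehicle at each time, high against low dose at each time, vehicle at 33 h against 9 h, and the difference of each dose effect between times. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the tested transcripts. Fitted log2 fold changes include a prior count of 0.125; where a group was at 0 in every library, a bound was computed on CPM over TMM-scaled library sizes, with 3 counts per library as the floor. Standard errors are the log2 fold change over the square root of the F statistic. Counting intervals are exact Poisson intervals at 95% and, like the floors, cover counting error only.

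The rule for named items, set at the same stage as the gene lists, took the largest rises and falls among transcripts with adjusted p under 0.05, a mean of at least 5 CPM in the higher group, and each treated animal on the same side of each vehicle animal; its requirement of a gene symbol was dropped. From it, the largest rise and the largest fall of the high dose at 9 h and at 33 h are named, and the sizes of the other large changes at 9 h are given as ranges. Abundance classes (bounds of 1, 10, 100 and 1000 TPM) and the 100 most abundant transcripts were chosen after seeing the data. To keep the ranking free of the animals compared, both were set on the mean TPM of the vehicle animals of the other time. Shares of counts were compared by two-sided exact permutation tests over the 252 arrangements of 5 against 5 animals, adjusted over 7 comparisons. Principal components were computed on log2 CPM with a prior count of 2.

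The model was tested on simulated counts made from the vehicle means, dispersions and library sizes. With 200 transcripts changed in the low dose group at 9 h, among 17276 tested, it recovered 37.3% of those changed 1.5-fold, 77.6% of those changed 2-fold and 92.4% of those changed 4-fold; 12 of its 150 calls were false. In the 6 simulated comparisons without change no transcript was called.

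Alternatives fixed before the data were examined were size factors by median of ratios, no count filter, a stricter filter (1 CPM in 5 libraries), DESeq2 1.42.0, limma voom 3.58.1 with sample quality weights, a fit of the compared groups alone, thinning to the smallest total, an offset for effective transcript length, a minimum change of 2-fold, and leaving out each animal (for counts of calls, their overlap and the named transcripts). Scaling by library totals was added after seeing the data, as were leaving out a pair of 33 h animals and, for the share of the most abundant transcripts, 50 or 500 transcripts, TPM in place of counts, a ranking in the vehicle animals of the same time and leaving out each animal.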

Results

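Liver RNA was measured in 30 Hartley guinea pigs, an outbred laboratory breed, given saline vehicle (3 ml/kg) or thioacetamide at 25 mg/kg (the low dose) or 100 mg/kg (the high dose). Thioacetamide is a compound that liver enzymes oxidise to reactive products and that is used in animals to produce liver injury. Livers were taken at 9 h or 33 h, which gave 6 groups of 5 animals, each animal being 1 library. The purpose stated for the series was to obtain different degrees of liver injury, so the comparisons of interest were each dose with its own vehicle group at each time, the doses with each other, and the effect of each dose between the times. The deposited tables held estimated counts for 25824 transcripts per library, and library totals ran from 21352800 to 33842300 estimated counts. Mean totals per group lay between 26129900 ± 1505650 at the high dose, 9 h and 28531100 ± 3932960 in the vehicle animals at 9 h (SD, n = 5 each, all totals to 6 significant digits). Of the listed transcripts, 18239 passed the count filter and were tested. The tables identify transcripts by Ensembl identifier, and neither they nor the reference table used here pair these with gene names, so results are given for groups of transcripts defined by abundance, dose and time, and for 4 transcripts picked by a fixed rule.

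Treated libraries separated from vehicle libraries, and treated libraries separated by time, while the vehicle groups of the different times lay close together. The first principal component of log2 CPM held 19.6% of the variance and the second 13.1%. Vehicle animals scored -50.2 ± 7.80 at 9 h and -63.1 ± 3.91 at 33 h on the first component, against -1.18 ± 28.0 at the low dose and 75.3 ± 17.7 at the high dose, 33 h (SD, n = 5 each). At 9 h the doses overlapped on it, at 16.8 ± 7.46 (low) and 22.3 ± 5.98 (high, SD, n = 5 each). Their ranges were 8.66 to 27.0 and 15.4 to 29.2. On the second component the 9 h treated livers moved one way, to 35.5 ± 11.1 at the low dose and 66.3 ± 4.83 at the high dose, and the 33 h treated livers the other way, to -33.2 ± 6.42 and -44.3 ± 11.3, with the vehicle groups between them at -11.3 ± 2.97 and -12.9 ± 2.40 (SD, n = 5 each). At 33 h the spread within a dose was wide, since low dose animals ran from -39.3 to 38.0 and high dose animals from 51.1 to 98.8 on the first component.

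**Figure D1:**
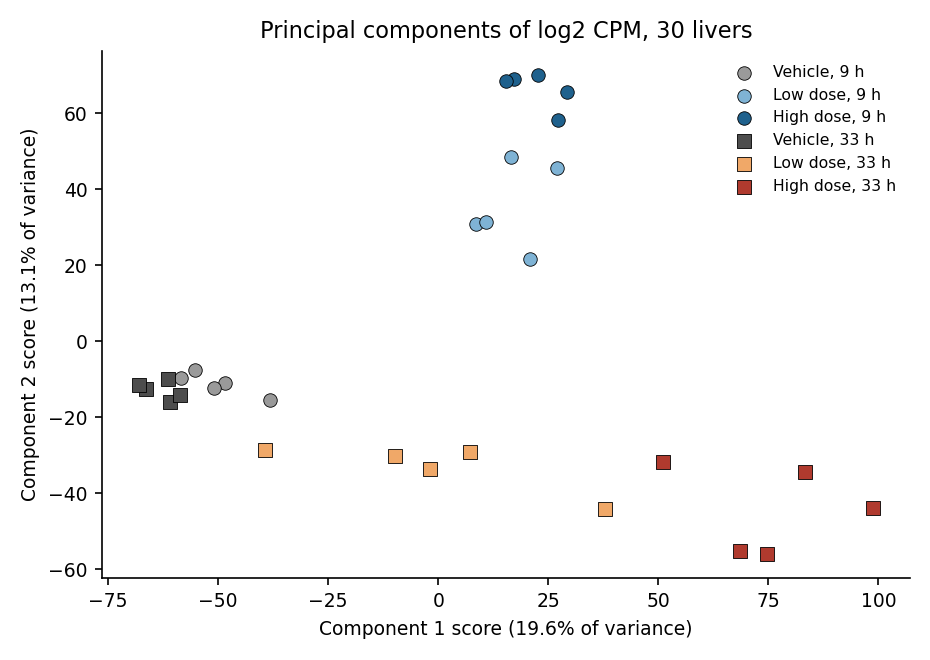
Scores of the 30 livers on the first (x axis) and second (y axis) principal components of log2 CPM over the 18239 tested transcripts, without units; each point is 1 animal, colour marks dose and shape marks time. Low dose animals at 33 h lie between -39.3 and 38.0 on the x axis and high dose animals at 33 h between 51.1 and 98.8.

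At 9 h after the low dose, 2466 transcripts were higher and 2038 lower than in vehicle livers, 4504 in all. Among larger changes the rises dominated, with 854 transcripts at least 2-fold higher and 177 at least 2-fold lower. That balance is partly set by the count floor, since a transcript near 0 in vehicle livers can rise but hardly fall. Transcripts at 10 to 100 TPM in the vehicle animals of the other time fell more often than they rose (968 against 582 of 4486), with a class median of -0.09 that was 0.04 after removing the TMM factors. The transcript with the largest rise by the naming rule at the high dose, 9 h, ENSCPOT00000033401.1, was already at 1.78 ± 0.467 TPM here, against 0.00942 ± 0.0136 TPM in vehicle animals (SD, n = 5 each), a fitted log2 fold change of 7.32 ± 0.92 (SE, adjusted p = 1.31e-06). The 6 largest rises by the rule had fitted log2 fold changes of 5.03 to 7.43 and the 6 largest falls -1.75 to -2.35. The edgeR quasi-likelihood test was used with adjusted p under 0.05, and these directions are relative to TMM scaling. With library totals in place of TMM the median of all transcripts moved to 0.13 and 76.1% of 4127 calls were rises, against 54.8% with TMM.

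The high dose at 9 h gave 2469 higher and 2327 lower transcripts, 4796 in all. As at the low dose, and with the same limit from the count floor, the large changes were mostly rises: 1210 transcripts were at least 2-fold higher and 280 at least 2-fold lower, and 584 were at least 4-fold higher against 57 at least 4-fold lower. The abundant transcripts moved little at this time. Of 129 transcripts above 1000 TPM 7 rose and 2 fell, and of 805 at 100 to 1000 TPM 72 rose and 55 fell. ENSCPOT00000033401.1, a transcript of 3111 bases, had the largest rise by the rule. Its level was 3.08 ± 1.63 TPM (SD, n = 5), and its fitted log2 fold change was 8.28 ± 0.93 (SE, adjusted p = 1.19e-07). The 5 vehicle libraries together held 3 counts of it and the 5 treated ones 1011, a ratio of 372 with a 95% counting interval of 127 to 1805 (exact Poisson). The largest fall was that of ENSCPOT00000005665.3, which measured 1.64 ± 0.730 TPM at the high dose and 12.3 ± 10.4 TPM in vehicle animals (SD, n = 5 each), a log2 fold change of -2.86 ± 0.60 (SE, adjusted p = 0.000608). The 6 largest rises at this dose had fitted log2 fold changes of 7.05 to 8.28 and the 6 largest falls -2.40 to -2.86. The vehicle values of ENSCPOT00000005665.3 ran from 3.51 to 24.9 TPM, all above the highest treated value of 2.65 TPM, a separation that the naming rule requires.

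**Figure D2:**
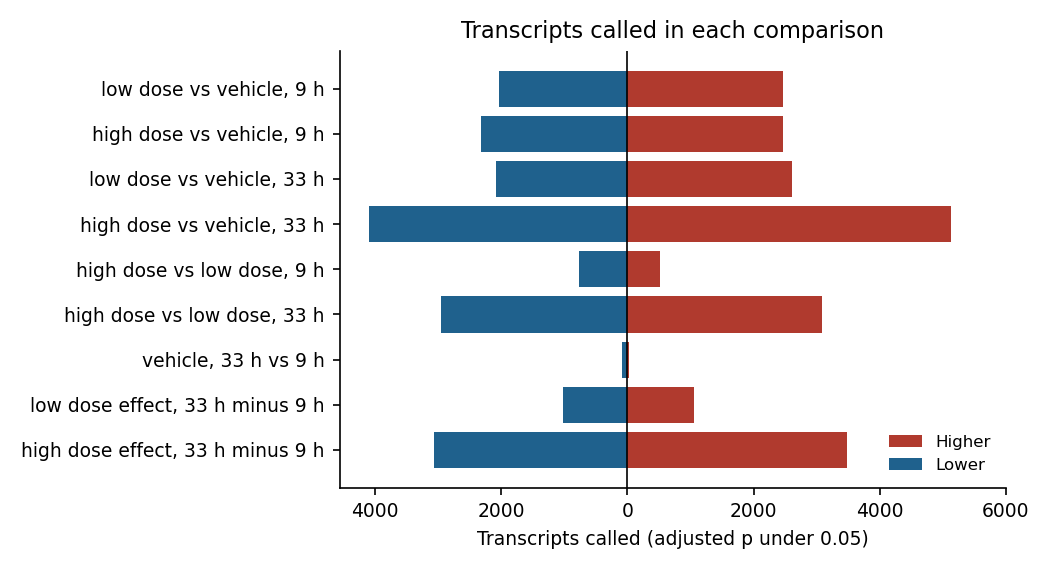
Number of transcripts called by the edgeR quasi-likelihood test (x axis, transcripts at adjusted p under 0.05) in each of the 9 comparisons (y axis), with bars to the right for transcripts higher in the group named first, or with a more positive effect, and bars to the left for lower. The high dose at 33 h has the longest bars, 5138 higher and 4103 lower, and the vehicle comparison the shortest, 27 and 79.

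Set directly against each other at 9 h, the doses differed in 1292 transcripts, 522 higher and 770 lower at the high dose, a balance that turned with the fit. With the 10 animals compared fitted alone the count was also 1292 but with 672 higher, so that rises were 52.0% of calls there, 48.5% with limma voom and 40.4% in the model of all animals. In the model of all animals, 162 were at least 2-fold higher and 49 at least 2-fold lower. Transcripts that had risen at both doses were more often without a detected difference between doses (1524) than further raised at the high dose (172). For falls the numbers were 1093 and 89. Whether or not the low dose was called, 338 rises and 468 falls at the high dose went beyond the low dose. Whether or not the high dose was called, 158 rises and 139 falls at the low dose went beyond the high dose. ENSCPOT00000033401.1 was not called between the doses, with a log2 difference of 0.96 ± 0.59 (SE, adjusted p = 0.369). Abundant transcripts leaned upward in this comparison, with 40 of 805 at 100 to 1000 TPM higher and 1 lower. With library totals in place of TMM that lean was 9 higher and 6 lower, and the whole comparison moved to 12.8% rises among 1994 calls. This count also rested on single animals, falling to 805, 837 or 728 without low dose animal 1, 2 or 3 and to 648 or 783 without high dose animal 3 or 4.

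At 33 h the low dose gave 2608 higher and 2086 lower transcripts, 4694 in all, with 649 at least 2-fold higher and 293 at least 2-fold lower. With only the compared groups fitted, 3763 were called. With TMM the abundant transcripts of the vehicle liver were now predominantly lower. Of 123 transcripts above 1000 TPM, 73 fell and 2 rose, with a median log2 fold change of -0.57; with library totals 47 fell and 10 rose, with a median of -0.25. Of 800 at 100 to 1000 TPM, 368 fell and 57 rose with a median of -0.31, but with library totals this class was nearly balanced, 206 falls against 186 rises with a median of 0.01. The 100 most abundant vehicle transcripts held 34.7 ± 2.70% of counts at the low dose and 40.5 ± 2.16% in vehicle livers (SD, n = 5 each), a lower share in each of the 5 treated animals than in any vehicle animal (two-sided exact permutation test, p = 0.00794, the smallest that 252 arrangements allow, adjusted p = 0.0278 over 7 comparisons). ENSCPOT00000000420.3 was at 0 in all 5 low dose livers and at 19.8 ± 9.71 TPM in the vehicle livers (SD, n = 5), at least 238-fold lower when 3 counts per library are taken as the floor. With library totals the median of all transcripts moved to 0.36, the count rose to 7434 and 90.5% of calls were rises.

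The high dose at 33 h changed more transcripts than any other comparison made here. It gave 5138 higher and 4103 lower transcripts, 9241 in all or 50.7% of those tested, with 2069 at least 2-fold higher and 1653 at least 2-fold lower. With only the compared groups fitted, 8124 were called. Transcripts that dominate the vehicle liver fell. Of 123 above 1000 TPM, 102 were lower and 3 higher, with a median log2 fold change of -1.07 and quartiles of -1.62 and -0.58. Of 800 at 100 to 1000 TPM, 510 were lower and 106 higher. Counts are relative, so these are falls in the share of the sequenced RNA, and the amount of RNA per liver was not analysed here. The 100 most abundant vehicle transcripts held 30.6 ± 3.79% of counts against 40.5 ± 2.16% in vehicle livers (SD, n = 5 each), lower in each treated animal than in any vehicle animal (two-sided exact permutation test, p = 0.00794, adjusted p = 0.0278). More transcripts reached 10 counts, 17252 ± 144 against 16116 ± 231 (SD, n = 5 each, two-sided exact permutation test, p = 0.00794, adjusted p = 0.0278). A smaller share in the most abundant transcripts leaves more counts for the others, so this is not separate evidence.

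The largest rise by the rule at the high dose, 33 h, was that of ENSCPOT00000005331.3, a transcript of 4719 bases, at 4.28 ± 2.36 TPM (SD, n = 5). It was at 0 in all 5 vehicle livers of that time, which makes it at least 92.9-fold higher with 3 counts per library as the floor (edgeR adjusted p = 2.01e-05). In vehicle livers at 9 h, however, it measured 0.282 ± 0.245 TPM (SD, n = 5), so it was detected in vehicle livers at the other time. ENSCPOT00000000420.3, of 1496 bases, had the largest fall, from 19.8 ± 9.71 to 0.0330 ± 0.0739 TPM (SD, n = 5 each, adjusted p = 4.91e-05), a call that was lost with limma voom (adjusted p = 0.302). Among vehicle livers at 9 h the same transcript ran from 0 to 22.1 TPM, a range wider than the difference of the 33 h means. Estimated counts are divided among transcripts that share sequence, which limits what the level of a single transcript shows. ENSCPOT00000033401.1 was still higher than in vehicle livers, at 0.779 ± 0.512 TPM (SD, n = 5), with a log2 fold change of 5.21 ± 0.88 (SE, adjusted p = 1.71e-05). The balance of directions at this time depended on the scaling. With library totals the median of all transcripts was 0.70, 86.8% of 11939 calls were rises, and 431 transcripts were called with the opposite sign to that under TMM. The 123 transcripts above 1000 TPM still had 65 falls against 19 rises with library totals, with a smaller median of -0.47, while those at 100 to 1000 TPM were nearly balanced, with 341 falls and 281 rises.

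**Figure D3:**
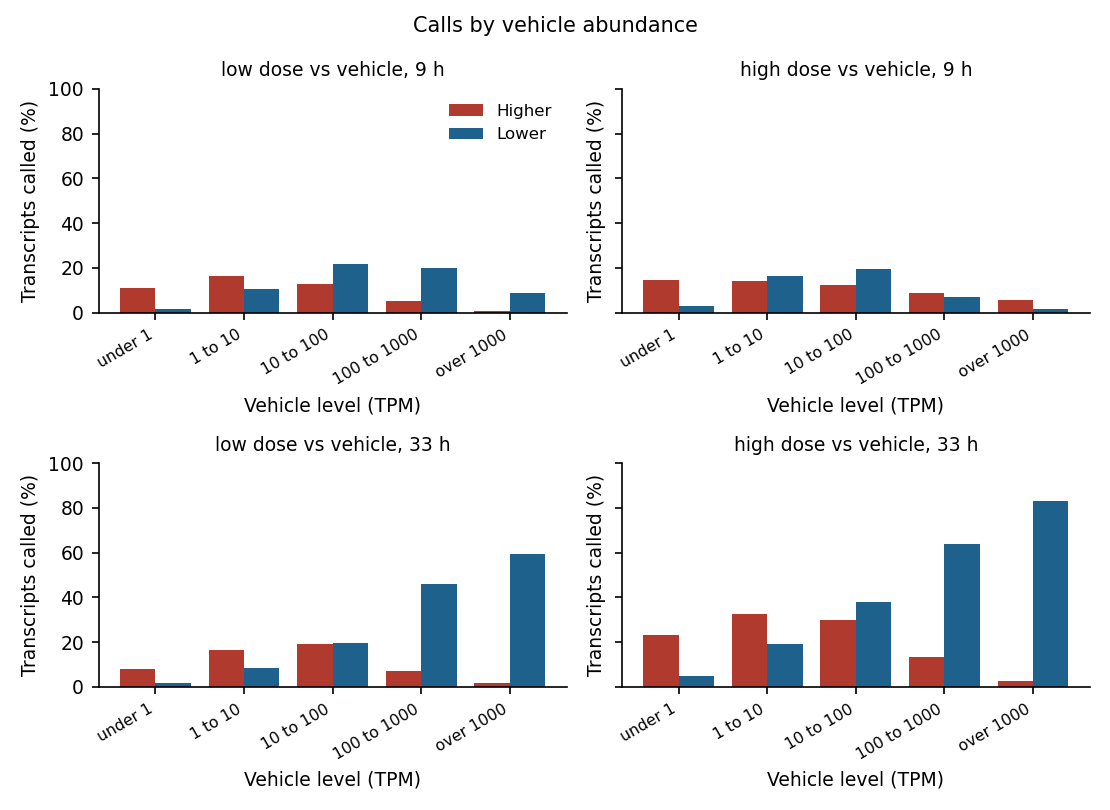
Share of transcripts called higher or lower (y axis, percent of the class) by level in vehicle livers (x axis, TPM classes set on the vehicle animals of the other time) for each dose and time, with TMM scaling; under 1 TPM the balance of directions is not read, because falls from near the count floor can hardly be called and the filter by group keeps transcripts that reach its minimum in treated animals alone. Above 1000 TPM the share called lower was 8.53% and 1.55% at 9 h and 59.3% and 82.9% at 33 h for the low and the high dose; with library totals these were 5.43%, 1.55%, 38.2% and 52.8%, and at 33 h after the low dose the median of the 100 to 1000 TPM class changed sign.

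**Figure D4:**
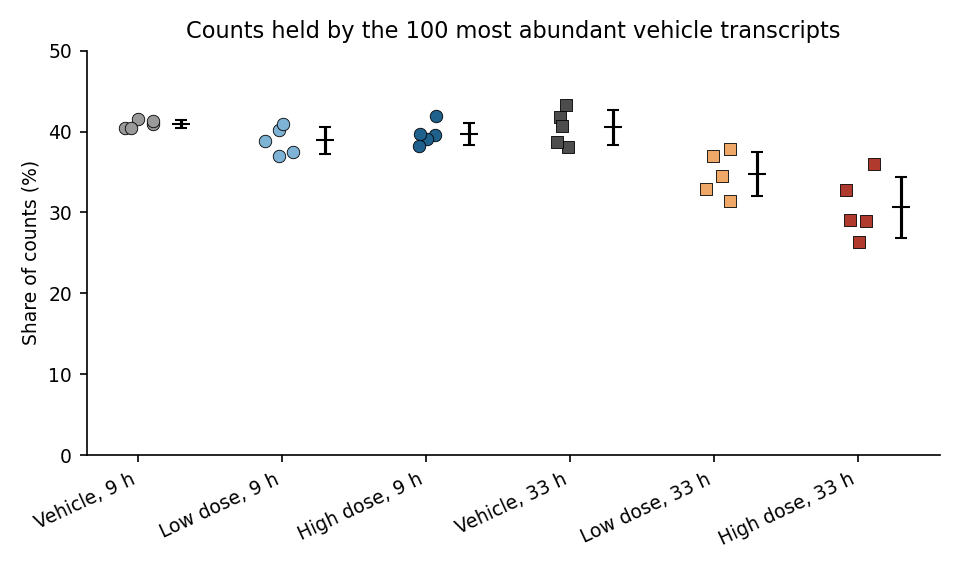
Share of unscaled estimated counts (y axis, percent) held by the 100 most abundant vehicle transcripts, ranked in the vehicle animals of the other time, for each group (x axis); points are animals and bars the mean ± SD (n = 5). Means were 40.9%, 38.9% and 39.7% at 9 h and 40.5%, 34.7% and 30.6% at 33 h for vehicle, low and high dose.

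The doses diverged at 33 h. The high dose livers had 3088 transcripts higher and 2962 lower than the low dose livers, 6050 in all, of which 939 were at least 2-fold higher and 640 at least 2-fold lower. With only these groups fitted, 4350 were called. Of transcripts raised at both doses, 806 were raised further at the high dose and 1399 showed no detected difference. Of transcripts lowered at both, 1104 were lowered further and 717 showed no detected difference. Among 123 transcripts above 1000 TPM, 67 were lower at the high dose and 4 higher, with a median log2 difference of -0.58; with library totals 51 were lower and 17 higher, with a median of -0.31. The share of counts in the 100 most abundant vehicle transcripts, -4.12 percentage points apart (30.6% minus 34.7%), did not pass an exact permutation test (two-sided p = 0.0873, adjusted p = 0.144). Without high dose animal 5 the difference was -5.47 points and passed before adjustment (exact permutation test, p = 0.0317), as did the shares of the 500 most abundant transcripts (-6.94 points) and of TPM (-4.17 points). It did not pass for the 50 most abundant (-2.61 points, exact p = 0.238), with the ranking of the same time (-4.35 points, exact p = 0.0794), or without any other single animal (-4.95 to -3.04 points). ENSCPOT00000033401.1 was higher at the high dose by 3.78 ± 0.74 on the log2 scale (SE, adjusted p = 0.000317), and ENSCPOT00000005331.3 by 3.05 ± 1.01 (SE, adjusted p = 0.0226). With library totals, 82.1% of 7537 calls were rises, against 51.0% with TMM.

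Vehicle livers differed little between the times. Between the vehicle groups, 27 transcripts were higher and 79 lower at 33 h than at 9 h, 106 in all, and 22 of them changed at least 2-fold. None of the 4 named transcripts passed the test between the vehicle groups. ENSCPOT00000005331.3 came closest, at 0 at 33 h and 0.282 ± 0.245 TPM at 9 h (SD, n = 5, adjusted p = 0.0612). The count was unstable, being 23 in a fit of these 10 animals alone, 470 with DESeq2 and 236 with limma voom. It fell to 62, 57 or 39 without 33 h animal 1, 2 or 5 and to 54 or 64 without 9 h animal 3 or 4, and rose to 258 without 33 h animal 4.

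The effect of the low dose differed between times for 2067 transcripts, 1053 with a more positive and 1014 with a more negative effect at 33 h. Of these, 555 were called higher at 9 h but not at 33 h, 467 were called lower at 9 h but not at 33 h, 566 were called higher at 33 h but not at 9 h, and 398 were called lower at 33 h but not at 9 h. These numbers overlap, since 64 transcripts called higher and then lower and 88 called lower and then higher are counted under both times, and a missing call does not show a missing change. A further 860 transcripts were raised and 678 lowered at both times with no detected difference in size. ENSCPOT00000033401.1 was among those called higher at 9 h alone. Its log2 fold change of 7.32 at 9 h became 1.43 ± 1.05 at 33 h (SE, adjusted p = 0.356), and the difference passed the test (adjusted p = 0.0310). With library totals, 80.6% of 2943 differences were more positive at 33 h.

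The effect of the high dose differed between times for 6548 transcripts, 3480 more positive and 3068 more negative at 33 h. Among these, late changes outnumbered early ones. There were 2464 that rose at 33 h and had not been called higher at 9 h, and 2159 that fell at 33 h and had not been called lower at 9 h. Early changes not called in the same direction at 33 h came to 594 rises and 923 falls. The 163 transcripts called higher and then lower and the 372 called lower and then higher are counted as both early and late. Outside these, changes called at both times without a detected difference in size came to 1034 rises and 733 falls. ENSCPOT00000033401.1 was higher at both times, and the difference of -3.07 ± 1.63 on the log2 scale did not pass the test (SE, adjusted p = 0.148). With library totals, 86.9% of 9718 differences were more positive at 33 h, against 53.1% with TMM.

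The high dose calls of the 9 h and 33 h comparisons, which share no animal, overlapped in 2452 transcripts of the same sign. There were 1464 raised at both times, against 696 expected of independent lists (one-sided Fisher's exact test across transcripts, p = 1.98e-269), and 988 lowered at both, against 523 expected (p = 4.35e-119, Fisher's exact test). The balance of directions depended on the scaling here too, since with library totals 1818 of 2161 shared calls were rises. Transcripts are not independent replicates, so these p-values overstate the evidence. The expected numbers also take each transcript as equally likely to be called in each direction. At the high dose, transcripts under 1 TPM rose in 14.7% and fell in 2.81% at 9 h. At 33 h these were 23.1% and 5.02%. How far this adds to the overlap of the same sign was not tested. Opposite changes were rarer than expected of independent lists, with 163 raised and then lowered (555 expected) and 372 lowered and then raised (656 expected). For the low dose, 976 transcripts were raised and 714 lowered at both times, against 353 and 233 expected.

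**Figure D5:**
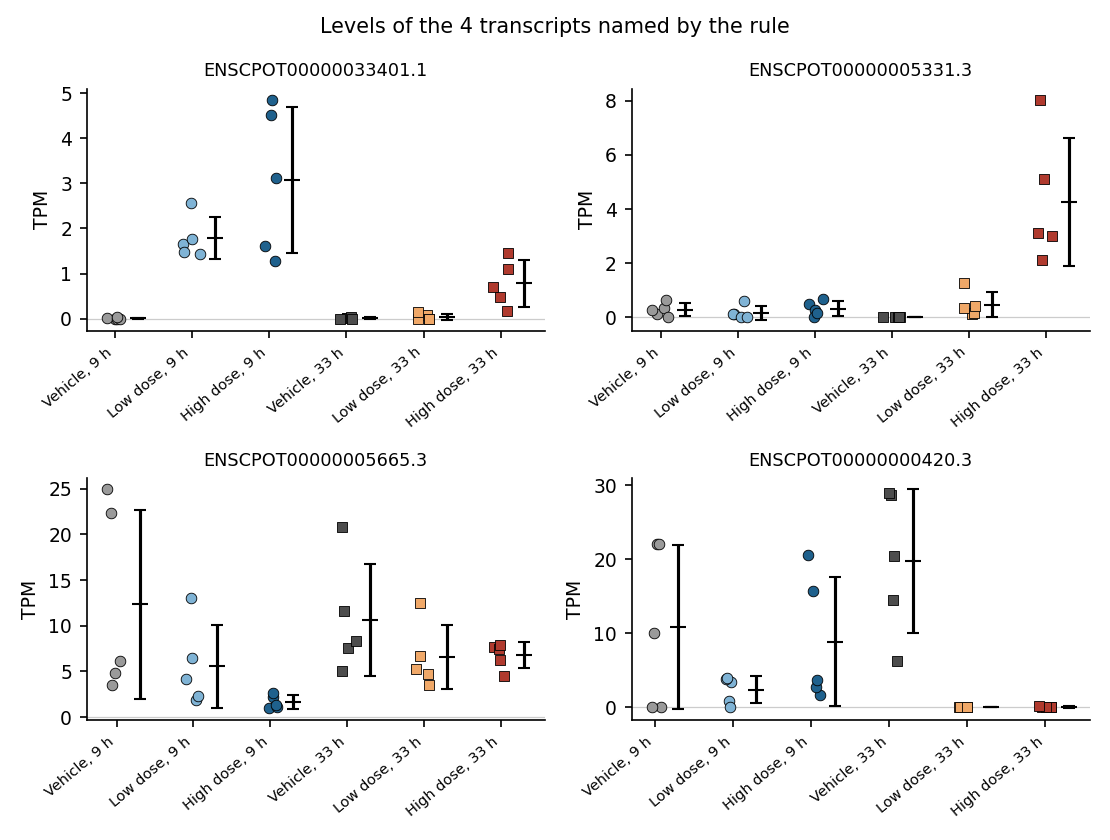
Level of each of the 4 named transcripts (y axis, TPM) in the 6 groups (x axis); points are animals and bars the mean ± SD (n = 5). ENSCPOT00000033401.1 was highest at the high dose, 9 h (3.08 TPM), ENSCPOT00000005331.3 at the high dose, 33 h (4.28 TPM), ENSCPOT00000005665.3 was lowest at the high dose, 9 h (1.64 TPM), and ENSCPOT00000000420.3 was at or near 0 in both treated groups at 33 h.

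The low and high dose comparisons of 1 time share their vehicle animals. At 9 h 2906 transcripts were called at both doses with the same sign and 3 with opposite signs; at 33 h the numbers were 4055 and 14. Independent lists would share 334 rises and 260 falls at 9 h and 735 rises and 469 falls at 33 h. In 10 simulations of unchanged groups against shared controls no transcript was called at both doses. With nothing changed, few calls are made at either dose. This result therefore does not show how far shared controls add to the overlap of real calls. When the vehicle animals were divided so that each dose had its own, over 20 divisions the shared calls were 1395 to 1667 at 9 h and 1881 to 2829 at 33 h. The covariance of log2 fold changes across transcripts was 0.84 at 9 h and 0.81 at 33 h, against 0.17 and 0.17 in the simulations. With divided vehicle animals it was 0.74 to 0.81 at 9 h and 0.65 to 0.73 at 33 h. The correlation was 0.76 at 9 h and 0.70 at 33 h, against 0.51 and 0.50 in the simulations. With divided vehicle animals, and so fewer per dose, the correlation was 0.37 to 0.43 at 9 h and 0.31 to 0.37 at 33 h.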

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

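The tests of scaling, of a common factor and of exchanged low and high dose labels were chosen after the results were seen; the test of gained counts, the exchange of vehicle and low dose labels and the splits of the animals were set before theirs. Within groups of 5, 60 sets of values were examined for a single animal far from the rest, and 3 stood out, which is the number chance gives (1 in 20). For ENSCPOT00000005331.3 the highest animal's gap to the next was 0.802 of the range in the low dose group at 9 h and 0.755 in the low dose group at 33 h. For ENSCPOT00000000420.3 in the high dose group at 33 h it was 1, since 4 of the 5 animals were at 0 there.

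The effect of dose differed between 9 h and 33 h, by the interaction test, for 2067 transcripts at the low dose and 6548 at the high dose. Among the named transcripts the low dose effect differed for ENSCPOT00000033401.1 (edgeR adjusted p = 0.0310), ENSCPOT00000005331.3 (adjusted p = 0.0116) and ENSCPOT00000000420.3 (adjusted p = 0.0185). The high dose effect differed for ENSCPOT00000005331.3 (edgeR adjusted p = 0.000388) and ENSCPOT00000000420.3 (adjusted p = 0.000750). These transcripts were named for large high dose changes at 1 of the times in the same data, which favours such differences. For ENSCPOT00000005331.3 much of the low dose difference lay in the vehicle livers, at 0.282 TPM at 9 h and 0 at 33 h. Low dose livers had means of 0.165 TPM at 9 h and 0.463 TPM at 33 h.

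Abundant vehicle transcripts fell at the high dose, 33 h, as a share of the sequenced RNA; whether their amount per liver fell is open, since counts are relative. TMM factors as the whole source of the falls called above 1000 TPM are argued against by the calls with library totals. These were 65 lower and 19 higher of 123. The share of the 100 most abundant transcripts, which uses no scaling factor, differed by -9.90 percentage points. For transcripts at 100 to 1000 TPM 42.6% were called lower with library totals against 35.1% called higher. There the scaling and the fall cannot be told apart. A few transcripts taking up the counts is argued against by the 698 transcripts needed to make up 50% of the 25.0 percentage points gained. A single dilution factor for all transcripts above 1000 TPM is argued against by an SD of 0.82 in their log2 fold changes. The typical SE for 1 transcript was 0.15. RNA of other cells need not lower all of them by 1 factor, since such cells can hold some of the same transcripts. A change of cell composition was therefore not tested. Alone or together with lower expression of some transcripts, which may differ with dose, it stays open as a hypothesis, since marker genes could not be looked up.

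At 33 h the animals of neighbouring groups came close, low dose animal 4 at 38.0 and high dose animal 5 at 51.1 on the first component. If these labels had been exchanged, putting them back should have raised the number of calls between the doses. Over the 25 possible exchanges the highest count was 3309, for that very pair, against 4350 with the labels as given (fits of these 10 animals). Between vehicle and low dose the highest count over 25 exchanges was 3, against 3763. An exchange within these groups is therefore argued against, and animals that responded to different degrees are a candidate explanation that was not tested.

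At 9 h after the low dose, transcripts at 100 to 1000 TPM were called lower more often than higher (159 against 43 of 805). With library totals 11.2% were called lower and 8.45% higher, so the excess of falls and the scaling cannot be told apart: the smaller excess that remains neither vanishes nor reaches 2 times the rises.

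In fits of the compared animals alone, 100 splits were drawn per comparison (60 of 31752 for each difference between times). Only 1 of them, the real one, gave as many calls. For comparisons of 2 groups this argues against chance as the source of the number of calls. The share used was 0.05, unadjusted over the 9 comparisons. For the differences between times, the splits shuffled the times within treated and within vehicle animals. They cannot tell a difference of dose effects from other changes with time. With so few drawn, the share of splits with as many calls can be no smaller than 1 in 100 or 1 in 60. Splits that were not drawn are not excluded. The real count and the highest of the other splits were 4559 and 3 for the low dose and 4483 and 2 for the high dose at 9 h, 3763 and 3 for the low dose and 8124 and 2 for the high dose at 33 h, 1292 and 57 between doses at 9 h, 4350 and 3309 between doses at 33 h, and 23 and 3 between the vehicle groups. For the differences between times they were 2126 and 1930 at the low dose and 5986 and 2 at the high dose. The 1930 lay close to the real count, so chance is not excluded for the low dose difference.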

How the results depend on the processing

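Scaling by library totals, leaving out a pair of 33 h animals and each alternative for the share of the most abundant transcripts were chosen after seeing the data. Counts of calls stayed within 1.5 times under median-of-ratios factors, no filter, the stricter filter, thinning and the length offset (9 or 10 of the counts each), at 0.736 to 1.13 times. Requiring a 2-fold change lowered each, by construction, to 1031 and 1490 for the low and high dose at 9 h, 942 and 3722 at 33 h, 211 and 1579 between doses at 9 h and 33 h, 22 between vehicle groups, 642 and 2974 for the differences between times, and 677 for the overlap of high dose calls. Library totals gave 7434 for the low dose at 33 h and 1994 between doses at 9 h, with rises at 90.5% and 12.8% of calls. They moved the share of rises by over 10 percentage points also for the low dose at 9 h (76.1%), the high dose at 33 h (86.8%), the doses at 33 h (82.1%), the vehicle groups (15.1% against 25.5%) and the differences between times (80.6% and 86.9%), and left 1818 rises in an overlap of 2161 (1464 of 2452 with TMM). limma voom gave 2541 between doses at 9 h and 236 between vehicle groups; DESeq2 gave 470 and the 10 vehicle animals alone gave 23 for the latter. Rises went from 40.4% to 52.0% of calls, a turned majority, between doses at 9 h with these groups alone, and from 25.5% to 39.1% (DESeq2), 39.4% (limma voom) and 39.5% (without 33 h animal 4) between vehicle groups. Fitting the compared groups alone lowered the 33 h counts to 3763 (low dose), 8124 (high dose) and 4350 (between doses). At 9 h it gave 4559, 4483 and 1292 for the same comparisons. The causes were not tested. Without both low dose animal 4 and high dose animal 5 the 33 h counts were 3725 (low dose), 9326 (high dose) and 6884 (between doses).

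With each animal left out in turn the counts ran from 3854 to 4146 and 4301 to 4537 for the low and high dose at 9 h, 3512 to 4952 and 8590 to 9332 at 33 h, 648 to 1485 and 4780 to 6562 between doses at 9 h and 33 h, 39 to 258 between vehicle groups, 1661 to 2030 and 6045 to 6788 for the differences between times, and 2226 to 2477 for the overlap. The named transcripts kept direction and call in 18 of 18 alternatives for 3 of them. ENSCPOT00000000420.3 did so in 17, and lost its call with limma voom (log2 fold change -10.18, adjusted p = 0.302, range over alternatives 1.18e-08 to 0.302). The naming rule placed each treated animal on the same side of each vehicle animal, so direction with an animal left out was fixed in advance. The 33 h share of the 100 most abundant transcripts fell at both doses under each alternative, differing from vehicle by -6.56 to -4.95 (low) and -11.3 to -8.82 (high) percentage points with animals left out. At 9 h the low dose difference of -2.04 (exact permutation test, p = 0.0397, adjusted p = 0.0926) passed before adjustment only, lost that for 50 transcripts (-1.18) and for TPM (-0.889) and without any single vehicle animal (-2.17 to -1.87), and was larger for 500 transcripts (-3.44, exact p = 0.00794); the high dose difference of -1.24 passed without high dose animal 4 (-1.78) and for 500 transcripts (-1.66, exact permutation test, p = 0.0476). Between doses at 33 h the share (-4.12, not passing) passed for 500 transcripts (-6.94), for TPM (-4.17) and without high dose animal 5 (-5.47), but not for 50 transcripts (-2.61), with the ranking of the same time (-4.35) or without any other animal (-4.95 to -3.04). Gene sums and tests of gene lists were not run, since no gene names were matched. No paired analysis was possible because replicate numbers only name animals. Depth limits rare transcripts: 3 counts are 0.140 CPM, before TMM scaling, in the smallest library.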

Other observations

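At the high dose some transcripts moved in opposite directions at the different times: 372 were lower at 9 h and higher at 33 h, and 163 were higher at 9 h and lower at 33 h. Each of these 535 also passed the test of the difference between times. That adds no support, since calls of opposite sign in the same model all but ensure it. At the low dose the numbers were 88 and 64. The number of transcripts with at least 10 counts rose at 33 h with dose, from 16116 ± 231 in vehicle livers to 16718 ± 272 at the low dose and 17252 ± 144 at the high dose (SD, n = 5 each). The low dose exceeded vehicle by 602 transcripts (exact permutation test, two-sided p = 0.0159, adjusted p = 0.0370). The high dose exceeded the low dose by 534 transcripts in an exact permutation test (two-sided p = 0.00794, the smallest possible, adjusted p = 0.0278). At 9 h the means were 16237 ± 276, 16721 ± 384 and 16627 ± 81.9 (SD, n = 5 each), and neither dose passed after adjustment (exact permutation tests, adjusted p = 0.100 and 0.0694).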
